A study of Homo sapiens with 12 samples.

How the data were processed

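RNA bound to YTHDF2, a reader protein of N6-methyladenosine (m6A) in mRNA, was recovered by immunoprecipitation (IP) from U251-MG cells, a human astrocytoma line labelled as astrocytes, and sequenced beside the RNA of the lysates it came from (input). Per the labels, cells were kept in medium with 2% serum, without manganese or with 100 µM manganese chloride. Each of the 4 groups (control input, manganese input, control IP, manganese IP) held 3 libraries, 12 in all. Per the labels' protocols, cells were lysed in a buffer with NP-40, the lysate was cleared by centrifugation, a small part was kept as input and purified for poly(A) RNA, and the rest was incubated with a YTHDF2 antibody. Stranded mRNA libraries were read as pairs on a HiSeq instrument. The labels name no IP with a control antibody and give neither the length of exposure nor whether replicates were separate cultures.

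Per the labels' protocols, the authors quantified transcripts with kallisto on hg19; no version is stated. The deposited gene table holds estimated counts per Ensembl gene, rounded by the authors to whole numbers. The authors deposited the same genes as TPM summed from transcripts. A transcript table, deposited as estimated counts and as TPM, holds 153329 transcripts and does not pair them with genes. A deposited analysis table gives the authors' mean log2 ratios of IP to input TPM for each treatment, and the authors' unadjusted p-value for the difference between treatments. A deposited summary gives fragment counts per library and the percent aligned, which per the file headers are totals, assigned fragments and their share.

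The gene table held 36963 genes. The deposited analysis table named 35185 of them, 27 whose names a spreadsheet had turned into dates were named from the reference gene table by Ensembl identifier, and 1751 had no name. At least 1 count was present for 23437 genes. The test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) on the estimated counts, with genes kept by filterByExpr (minimum count 10, minimum total 15), which left 14804, TMM factors over the 12 libraries, and 1 fit with a mean per group. Benjamini-Hochberg adjustment ran over all tested genes, with a threshold of 0.05. There were 6 contrasts: IP against input in control cells, in manganese-treated cells and averaged over both, manganese against control in the input and in the IP, and the change of enrichment with manganese, which is the difference between the 2 enrichments. Levels are given as CPM scaled by TMM factors, as mean ± SD of 3 libraries, and changes as log2 ± SE. Replicate numbers were not used as pairs in that fit. The p-values measure only the spread between these libraries.

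A total of 27 gene lists and the rule for naming genes were fixed before the data were examined, as were the tests and most alternatives. Lists were JNK pathway, m6A writers, erasers and readers, mRNA deadenylation and decay, NF-kB and inflammatory mediators, interferon response, metallothioneins and zinc response, manganese and iron handling, NRF2 and oxidative stress, integrated stress response and unfolded protein response, heat shock, p53 targets, hypoxia and glycolysis, cholesterol synthesis, cell cycle and mitosis, replication-dependent histones, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, nuclear-encoded respiratory chain, mRNAs known from other cells as m6A-modified or YTHDF2-bound, KRAB zinc finger transcription factors, non-polyadenylated and nuclear RNAs, astrocyte and glioma identity, extracellular matrix and adhesion, secretory pathway membrane and lysosome, and markers of neurons, of microglia and macrophages, and of epithelium. Lists were tested with camera of limma 3.58.1 (preset inter-gene correlation 0.01) on voom values, and beside it with an estimated correlation and with fry. Benjamini-Hochberg adjustment ran over the 24 lists with at least 5 measured members. Some genes stand on more than 1 list, for example SOD2, ATF3, FTL and CCND1.

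Genes were named where, per contrast, they passed the threshold, had a mean of at least 5 CPM over the libraries compared, had every library of 1 group above every library of the other (which chance gives for 10% of genes with 3 against 3), and were among the 12 largest changes in either direction without clone-type names. For the average, all inputs were set against all IPs. For the change of enrichment, the 3 differences between IP and input libraries of the same number had to separate by treatment. MAP2K4 (also called SEK1), MAPK8, MAPK9, JUN and YTHDF2 were named in any case, with the 4 members of each list with the smallest p. The text gives part of the genes that met this rule, and a gene left out on purpose is not reported here. Where all 3 libraries of a group were at 0, the fold is a lower bound against a floor of 3 counts over the group. Floors cover counting error only, and errors in assigning reads to genes, which could place a gene at 0, were not tested. Reads of pseudogenes, readthrough genes and close paralogs are shared out by the authors' quantification, so such genes are uncertain.

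The test was checked on simulated counts with 14804 genes, 100 changed by 1 and 100 by 2 on the log2 scale. For manganese against control in the input, 12% of the former and 57% of the latter were called, with 2 false calls among 71. For the change of enrichment, 3% and 23% were called, with 0 false calls among 26. In control enrichment 11% and 58% were called (2 false among 71), in manganese enrichment 15% and 52% (6 false among 73), and in the IP contrast 9% and 61% (1 false among 71).

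The alternatives were RLE factors, total counts alone, TMM without the 100 most abundant genes, no low-count filter, a filter of at least 1 CPM in 6 libraries, DESeq2 1.42.0, limma voom, a fit with a replicate block, a fit of only the libraries compared, each library left out in turn, and other set tests and set thresholds. Added after the data were seen were limma on log2(TPM + 1), scaling without PCGF6 and ENSG00000226958, a correction for transcript length, and leaving out control input 1 and control IP 3 together. Tests of single transcripts of the 5 genes named in any case, and gene counts summed from transcripts, were left out because no table pairs transcripts with genes. GC content was not examined because no sequence of this build was at hand.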

Results

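The 12 libraries measured poly(A) RNA of U251-MG astrocytoma cells and the RNA recovered with YTHDF2 from the same kind of lysate, 3 libraries per group. Total fragments ran from 23898352 to 35411833 per library. Estimated gene counts were 19585869, 25239710 and 24181904 in control input 1 to 3 and 22602890, 23396203 and 22784191 in manganese input 1 to 3. They were 25872265, 23132136 and 16683984 in control IP 1 to 3 and 28425552, 24864934 and 27365433 in manganese IP 1 to 3. In control IP 3, 56.88% of fragments were aligned, against 83.7% to 87.12% in the other libraries. A single gene, PCGF6, took 34.3% to 41.8% of the counts of every library. A short transcript, matched to it by its counts, held at least 99.99% of them. Whether these reads come from PCGF6 mRNA was not tested. Libraries of a group correlated with r of 0.880 to 0.968 (log2 CPM, across genes, which are not independent replicates). The first principal component held 29.9% of the variance and the second 26.0%. Control input 1, control IP 3 and manganese IP 3 stood apart from their groups on the third component. On the first component these libraries were also the outermost of their groups. Control IP 3 and manganese IP 3 stood apart on the fourth as well.

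The first question was which mRNAs were recovered with YTHDF2 from control cells. MAP2K4 (ENSG00000065559), the kinase also called SEK1 that activates JNK, had 264.9 ± 9.32 CPM in the IP against 77.6 ± 2.47 in the input (SD, n = 3), a log2 enrichment of 1.77 ± 0.18. JUN (ENSG00000177606), the transcription factor that JNK phosphorylates, was enriched by 1.41 ± 0.18 and YTHDF2 mRNA (ENSG00000198492) by 0.92 ± 0.16. C1orf216 (3.42 ± 0.23), HOXA5 (3.41 ± 0.40) and RGS2, a regulator of G-protein signalling (3.73 ± 0.32), were enriched more strongly. So were the mRNAs of the secreted proteins CTGF (3.41 ± 0.43) and CCL2, a chemokine (2.25 ± 0.32). The mRNA of ribosomal protein RPLP1 was at 23.0 ± 4.28 CPM in the IP and 399 ± 89.8 in the input, a log2 value of -4.12 ± 0.24. All of these passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p = 1.5e-05 for MAP2K4, 7.08e-05 for JUN and 0.000551 for YTHDF2. MAPK8 (JNK1, ENSG00000107643) was enriched by 0.86 ± 0.21 (edgeR, Benjamini-Hochberg adjusted p = 0.00561), but not with total counts as the scaling (0.0591) or on log2(TPM + 1) with limma (0.105). MAPK9 (JNK2, ENSG00000050748) had a log2 value of 0.04 ± 0.20, which did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.918). Its sign turned under 4 alternatives and without control input 1 (-0.13) or control IP 3 (-0.0041), and with the length correction it passed as enriched (0.63, adjusted p = 0.0394).

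Of 141 mRNAs of KRAB zinc finger transcription factors, 80 were higher in the control IP, 2 were lower and 59 did not pass (86 and 2 adjusted over the list alone). Their median was 1.01, with ZNF700 at 2.35. Of 32 mRNAs known from other cells as m6A-modified or YTHDF2-bound, 11 were higher and 1 lower (11 and 1 adjusted over the list alone), among them MAT2A (2.21), the long noncoding RNA TUG1 (1.88) and CCND1 (1.57). Both lists passed camera with Benjamini-Hochberg adjustment (adjusted p = 2.48e-16 and 0.0169), with adjusted p = 0.054 and 0.223 with an estimated correlation. The second of these list calls, with a median of 0.48, was lost without control IP 3 (0.0654, median 0.19) and without it and control input 1 (0.0689), and with the transcript length correction (0.366). Of 73 cytosolic ribosomal protein mRNAs, 68 were lower in the IP and 0 higher (68 and 0 adjusted over the list alone), with a median of -2.10 and RPL36 at -5.24. Of 53 mRNAs of the nuclear-encoded respiratory chain, 37 were lower and 4 higher (37 and 4 adjusted over the list alone), with a median of -1.46 and ATP5ME at -3.82. Of 13 mitochondrially encoded mRNAs, 10 were lower and 0 higher (12 and 0 adjusted over the list alone), with a median of -1.51. These 3 lists passed camera (Benjamini-Hochberg adjusted p = 2.92e-36, 1.89e-12 and 1.22e-05), with adjusted p = 0.268, 0.332 and 0.473 with an estimated correlation.

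Secretory pathway and lysosome mRNAs were lower in the control IP in 16 of 39 cases and higher in 2 (16 and 2 adjusted over the list alone, median -0.54). NRF2 and oxidative stress genes were lower in 10 of 26 and higher in 3 (11 and 3 adjusted over the list alone, median -0.39). Cholesterol synthesis genes were lower in 7 of 22 and higher in 1 (8 and 1 adjusted over the list alone, median -0.71). Their camera tests gave Benjamini-Hochberg adjusted p = 0.00168, 0.02 and 0.0448, and adjusted p = 0.607, 0.473 and 0.332 with an estimated correlation. Without control IP 3 none of these 3 list calls held (0.106, 0.106 and 0.152), nor without it and control input 1 (0.29, 0.135 and 0.29), and with the length correction the NRF2 (0.0861) and cholesterol (0.101) calls were lost. The cholesterol call was also lost without control input 1 (0.0769), manganese IP 2 (0.052) or manganese IP 3 (0.0524), with RLE factors (0.0502), with the filter of 1 CPM (0.0544) and with only the libraries compared (0.0676). Of 22 m6A writers, erasers and readers, 8 were higher and 1 lower (8 and 1 adjusted over the list alone), without a list call (camera, Benjamini-Hochberg adjusted p = 0.173). They included YTHDF1, a paralog of YTHDF2 (2.12 ± 0.19), and WTAP, a subunit of the m6A methyltransferase (1.72 ± 0.21). BLOC1S5-TXNDC5, a readthrough gene, was at 0 counts in the 3 control IP libraries and at least 549-fold lower than in the input. In total, 4639 of 14804 genes passed, 2543 higher and 2096 lower in the IP. With total counts as the scaling, which moves the median of all genes from 0.04 to -0.26, 1679 were higher and 3036 lower (35.6% higher against 54.8%), and with only the libraries compared 1636 and 1834. Enrichment rose with transcript length, with medians of -0.79 in the shortest and 0.69 in the longest decile of genes (Spearman's rho 0.358 across genes, which are not independent). The labels name no IP with a control antibody, so recovery not due to YTHDF2 is contained in every enrichment.

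**Figure D1:**
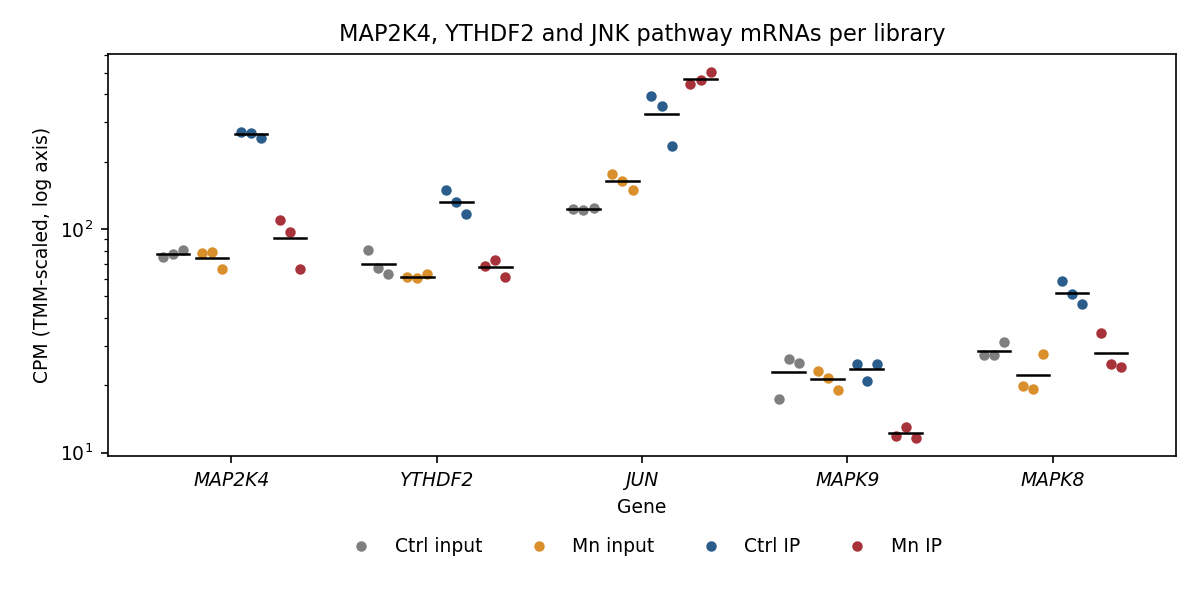
Levels of MAP2K4, YTHDF2, JUN, MAPK8 and MAPK9 in each of the 12 libraries, as TMM-scaled CPM on a log axis, with points for libraries and bars for group means. MAP2K4 averaged 264.9 CPM in the control IP and 74.3 to 90.8 CPM in the manganese groups, and was at 75.2 to 80.2 CPM in the control input libraries.

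The same comparison in manganese-treated cells asked which mRNAs were recovered after the exposure. JUN was enriched by 1.52 ± 0.18 and YTHDF1 by 1.78 ± 0.19 on the log2 scale (n = 3). PARN, a deadenylase, was at 96.3 CPM in the IP and 11.7 in the input (3.04 ± 0.32). CEBPB, a stress-induced transcription factor, was enriched by 2.60 ± 0.24 and JUND by 2.66 ± 0.33. MAP2K4 was at 90.8 ± 22.1 CPM in the IP and 74.3 ± 7.17 in the input, a log2 value of 0.29 ± 0.18 that did not pass. CDK1, the mitotic kinase (-2.97 ± 0.20), TMED2, a cargo receptor of the secretory pathway (-2.95 ± 0.18), and CYP51A1, a sterol demethylase (-2.63 ± 0.17), were depleted. In edgeR with Benjamini-Hochberg adjustment, adjusted p was 4.92e-05 for JUN, 1.65e-06 for CDK1, 0.243 for MAP2K4, 0.254 for MAPK8 (0.33 ± 0.21) and 0.559 for YTHDF2 (0.14 ± 0.15, and -0.016 with total counts). MAP2K4 passed without manganese IP 3 (0.51, adjusted p = 0.0278) and with the filter of 1 CPM (0.45, 0.0471), and was 0.16 without manganese IP 1. MAPK8 was 0.54 without manganese input 3 and 0.18 without manganese IP 1, and passed in neither. MAPK9 was lower in the IP by a log2 value of -0.81 ± 0.21 (edgeR, Benjamini-Hochberg adjusted p = 0.00923), which was lost without manganese input 1 (0.0696) or 2 (0.0547) and with the length correction (0.156).

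Of 73 ribosomal protein mRNAs, 38 were lower in the manganese IP than in the input and 0 higher (43 and 1 adjusted over the list alone, median -0.80). Respiratory chain mRNAs were lower in 15 of 53 cases and higher in 5 (17 and 6 adjusted over the list alone, median -0.51). Mitochondrially encoded mRNAs were lower in 10 of 13 and higher in 0 (10 and 0 adjusted over the list alone, median -1.29). The secretory pathway list had 18 of 39 lower and 2 higher (19 and 2 adjusted over the list alone, median -0.63). Manganese and iron handling had 8 of 20 lower and 0 higher (8 and 0 adjusted over the list alone, median -0.54). Cholesterol synthesis had 9 of 22 lower and 2 higher (9 and 2 adjusted over the list alone, median -0.62). Camera with Benjamini-Hochberg adjustment gave adjusted p = 4.77e-08, 0.026, 0.00119, 0.00352, 0.00573 and 0.0442 for these 6 lists in this order, and the largest adjusted p = 0.811 and the smallest 0.19 with an estimated correlation. Of the mRNAs known as m6A-modified or YTHDF2-bound, 13 of 32 were higher and 4 lower (14 and 5 adjusted over the list alone, median 0.73), with MAT2A at 1.41 ± 0.16 and TUG1 at 1.13 ± 0.18. Camera gave a Benjamini-Hochberg adjusted p = 0.0178 for them, and adjusted p = 0.19 with an estimated correlation. With the length correction the calls of the respiratory chain (0.575, median -0.050), of cholesterol synthesis (0.118, median -0.21) and of the m6A-modified or YTHDF2-bound list (0.11) were lost. The respiratory chain call was also lost without manganese IP 1 (0.0673), with fry (0.091), with the filter of 1 CPM (0.0578) and on log2(TPM + 1) (0.118). The cholesterol call was also lost without manganese IP 1 (0.0673) or 2 (0.0582), with total counts (0.051), with the filter of 1 CPM (0.0733), with only the libraries compared (0.0695) and with scaling without PCGF6 (0.0505). KRAB zinc finger mRNAs had 28 higher and 13 lower of 141 (27 and 13 adjusted over the list alone, median 0.06) and no list call (camera, Benjamini-Hochberg adjusted p = 0.495). OGFOD1 was at 0 counts in the 3 manganese IP libraries and at least 783-fold lower than in the input, and UPF1, a helicase of nonsense-mediated decay, at least 379-fold lower. The pseudogene FTH1P15 was at least 1720-fold lower, and AKAP8L, at 0 in the manganese input, at least 592-fold higher in the IP. These bounds take the assigned counts as they stand. In total, 4795 genes passed, 2187 higher and 2608 lower (45.6% higher). With total counts 1745 were higher and 3056 lower (36.3% higher), with a median of all genes of -0.18 against -0.03, and the majority turned with the filter of 1 CPM (2766 higher, 2176 lower), the length correction (2499 and 2097) and scaling without PCGF6 (2413 and 2367).

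Averaged over both treatments, 6237 genes passed, 3002 higher and 3235 lower in the IP, and 1545 and 1983 of them by at least 1 on the log2 scale. JUN was enriched by 1.47 ± 0.13, CCND1 by 1.56 ± 0.11, MAT2A by 1.81 ± 0.12, MAP2K4 by 1.03 ± 0.13, MAPK8 by 0.60 ± 0.14 and YTHDF2 by 0.53 ± 0.11. TRAM1, a protein of the endoplasmic reticulum translocon (-3.62 ± 0.22), TMED2 (-2.62 ± 0.13) and CAT, the catalase gene (-1.87 ± 0.12), were depleted. In edgeR with Benjamini-Hochberg adjustment, adjusted p was 1.75e-06 for JUN, 2.5e-05 for MAP2K4, 0.00163 for YTHDF2 and 0.00473 for MAPK8, the last of which was lost with total counts (0.0576) and on log2(TPM + 1) (0.0661). MAPK9 was lower by a log2 value of -0.38 ± 0.15 (edgeR, Benjamini-Hochberg adjusted p = 0.0485). This call was lost with RLE factors (0.0585), TMM without the 100 most abundant genes (0.0507), limma voom (0.0525), the filter of 1 CPM (0.101), no filter (0.113) and scaling without PCGF6 (0.0785), and the value was 0.11 with the length correction. It was also lost on leaving out any library except control input 1 or control IP 3 (adjusted p from 0.0687 to 0.149). With total counts, 2196 were higher and 4252 lower (34.1% higher against 48.1%), with a median of all genes of -0.28 against -0.05, and the majority turned with the filter of 1 CPM (3284 higher, 2849 lower) and the length correction (3013 and 2551). The enrichments of the 2 treatments share no library. In both, 1302 genes were higher in the IP, against 376 for independent lists, and 108 of the control-enriched genes were lower in the manganese IP. The lower genes shared 824 against 369, with 99 the other way. The log2 values correlated with r of 0.388 and rho of 0.438 across genes, which are not independent replicates.

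The study's central question was whether manganese changes the association of MAP2K4 mRNA with YTHDF2. Enrichment of MAP2K4 fell by 1.48 ± 0.25 on the log2 scale with manganese, from 1.77 to 0.29, and YTHDF2 mRNA fell by 0.78 ± 0.22, from 0.92 to 0.14 (n = 3 per group). JUN (0.11 ± 0.25, and -0.081 without control IP 3), MAPK8 (-0.54 ± 0.29, and -0.30 without manganese input 3) and MAPK9 (-0.84 ± 0.29) did not pass. Enrichment also fell for LATS1, a kinase of the Hippo pathway (-2.21 ± 0.40), and IFIT1, an interferon-induced protein (-1.68 ± 0.23). It fell for NFE2L2, the transcription factor NRF2 (-1.52 ± 0.24), and SOD2, the manganese superoxide dismutase (-1.36 ± 0.19). The log2 ratio of IP to input of CDK1 fell as well (-1.61 ± 0.26), but this mRNA was depleted rather than enriched in the manganese IP. Enrichment rose for HSPB1, a small heat shock protein (3.41 ± 0.44), BAX (2.67 ± 0.36), the metallothionein MT1E (2.17 ± 0.38) and TKT, transketolase (1.86 ± 0.25). MT1E mRNA was lower in the manganese input, so its gain need not reflect more RNA in the IP. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.00245 for MAP2K4, 0.0269 for YTHDF2, 0.818 for JUN, 0.229 for MAPK8, 0.0637 for MAPK9 and 0.00143 for IFIT1. The YTHDF2 call was lost without control input 2 (0.0807) or 3 (0.0834), manganese input 1 (0.0573), 2 (0.0563) or 3 (0.0585), or manganese IP 3 (0.0552), without the low-count filter (0.0718) and with the length correction (0.175). MAPK9 passed with the length correction (0.0339) and with DESeq2 (0.0484). In the authors' deposited table, the mean log2 ratios of MAP2K4 were 1.47 in control and 0.0139 in manganese.

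Ribosomal protein mRNAs gained in the IP relative to the input, with 33 of 73 higher and 0 lower (56 and 0 adjusted over the list alone, median 1.24), among them RPS16 (3.31 ± 0.41) and RPL35 (2.80 ± 0.36). Of the respiratory chain list 12 of 53 were higher and 0 lower (14 and 0 adjusted over the list alone, median 0.85), with NDUFS6 at 2.80 ± 0.36. Both lists stayed depleted in the manganese IP, with medians of -0.80 and -0.51 against the input. KRAB zinc finger mRNAs moved the other way, with 47 of 141 lower and 1 higher (65 and 1 adjusted over the list alone, median -1.07), among them ZNF700 (-2.07 ± 0.29) and ZNF12 (-1.87 ± 0.27). For these 3 lists camera with Benjamini-Hochberg adjustment gave adjusted p = 1.08e-27, 1.54e-09 and 5.58e-12, and adjusted p = 0.523, 0.523 and 0.133 with an estimated correlation. The respiratory chain call was lost with fry (0.0565), and its median was 0.52 without control IP 3. NRF2 and oxidative stress had 7 of 26 higher and 4 lower (10 and 4 adjusted over the list alone, median 0.61), with HMOX1, heme oxygenase, at 1.19 ± 0.23. The integrated stress and unfolded protein response had 7 of 29 higher and 5 lower (7 and 5 adjusted over the list alone, median 0.56), with SDF2L1 at 2.02 ± 0.31 and the chaperone DNAJB9 at -2.12 ± 0.36. Their camera tests gave Benjamini-Hochberg adjusted p = 0.0202 and 0.0404, with adjusted p = 0.523 with an estimated correlation for both, and neither held without control IP 3 (0.0523 and 0.0891, medians 0.31 and 0.42), without it and control input 1 (0.0678 and 0.102), with fry (0.0593 and 0.0779) or on log2(TPM + 1) (0.121 for both). The length trend of enrichment also differed between treatments, with a median change of 0.29 in the shortest and -0.60 in the longest decile of genes.

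In total 2531 genes changed enrichment, 1028 higher and 1503 lower. The majority turned with total counts, with 1261 higher and 1009 lower (55.6% higher against 40.6%, median of all genes 0.00 against -0.17), 1067 and 829 with the length correction (56.3%) and 1453 and 1215 with the filter of 1 CPM (54.5%). It did not turn with RLE factors (45.7% higher) or TMM without the 100 most abundant genes (40.8%). Without control input 2 or 3 the count was 1564 or 1526, without manganese input 1, 2 or 3 it was 1639, 1628 or 1455, and without control input 1 and control IP 3 together it was 3998. The lower genes were 2269 without control IP 3 and 972 without manganese IP 3, and the higher genes 1612 with DESeq2. Of the 1545 genes enriched on average by at least 1 on the log2 scale, 60 gained and 135 lost enrichment with manganese, with a median of -0.13. These were 3.88% and 8.74%, against 7.30% and 10.32% of the genes outside that set, whose median was -0.17. The enriched set thus did not lose enrichment more often than the rest. Of the 1983 depleted genes, 267 gained and 317 lost, with a median of -0.34. These were 13.46% and 15.99%, against 5.94% and 9.25% of the genes outside that set, whose median was -0.15. Neither set passed camera of limma, and the depleted set's median and its test differed in sign. Of 1678 genes enriched by at least 1 in control cells, 397 lost and 9 gained enrichment with manganese and 1033 were also enriched in manganese, but this set was chosen on control libraries that enter the change as well.

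**Figure D2:**
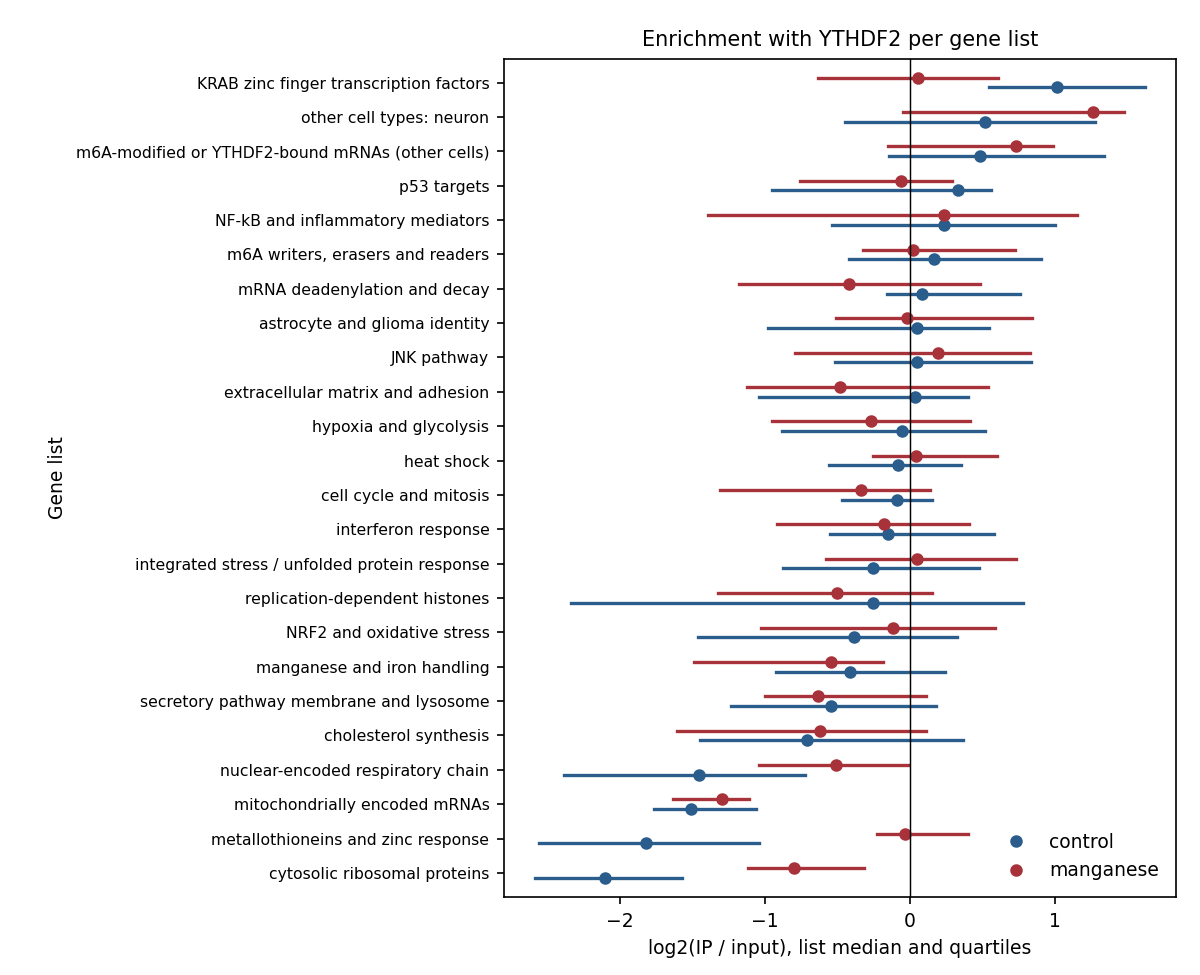
Median log2 enrichment (IP against input) of the members of each gene list in control and manganese-treated cells, with lines from the lower to the upper quartile. Ribosomal protein mRNAs lay at a median of -2.10 in control and -0.80 in manganese, and KRAB zinc finger mRNAs at 1.01 and 0.06.

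The input libraries showed what manganese did to mRNA levels. GPRC5A, a membrane receptor, rose from 6.58 ± 2.45 to 349 ± 26.1 CPM (SD, n = 3). IL11, a cytokine, rose from 1.64 ± 0.230 to 54.5 ± 4.57 CPM and HBEGF, a growth factor, from 5.02 ± 2.10 to 133 ± 3.68. The chemokine CXCL8 rose by 4.64 ± 0.51 on the log2 scale. GFAP, the intermediate filament of astrocytes, fell from 1734 to 214 CPM, a log2 change of -3.02 ± 0.20, and NES, the intermediate filament nestin, rose by 1.93 ± 0.18. MAP2K4 mRNA was at 77.6 and 74.3 CPM (-0.06 ± 0.18), and its level did not differ beyond the spread between replicates. In edgeR with Benjamini-Hochberg adjustment, adjusted p was 6.2e-07 for GFAP, 0.898 for MAP2K4, 0.534 for YTHDF2 (-0.19 ± 0.15), 0.838 for MAPK9 (-0.11 ± 0.20), 0.311 for MAPK8 (-0.37 ± 0.20) and 0.163 for JUN (0.41 ± 0.18). JUN passed without control IP 3 (0.00716), without it and control input 1 (0.0167) and with only the libraries compared (0.0081), and was -0.038 with total counts. MAPK8 was -0.61 without manganese input 3. With total counts YTHDF2 (0.00433) and MAPK8 (0.0102) passed, at -0.64 and -0.82, where all genes had a median of -0.49.

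Of 29 measured genes of the integrated stress and unfolded protein response, 27 rose, 0 fell and 2 did not pass (27 and 0 adjusted over the list alone, median 1.98), among them the amino acid transporter SLC7A5 (3.44 ± 0.16), DDIT4 (2.38 ± 0.15) and the disulfide isomerase PDIA4 (2.50 ± 0.19). Extracellular matrix and adhesion genes rose in 27 of 30 cases and fell in 0 (27 and 0 adjusted over the list alone, median 2.19), among them THBS2 (4.09 ± 0.20), ITGA5 (3.76 ± 0.20) and TGFBI (3.33 ± 0.19). Of the secretory pathway membrane and lysosome list, 36 of 39 rose and 0 fell (36 and 0 adjusted over the list alone, median 1.75), among them PSAP (2.23 ± 0.17) and the lysosomal cholesterol transporter NPC1 (2.88 ± 0.27). Hypoxia and glycolysis genes rose in 23 of 34 cases and fell in 0 (26 and 0 adjusted over the list alone, median 1.33), among them P4HA2 (4.62 ± 0.24), ADM (4.32 ± 0.29) and the glucose transporter SLC2A3 (2.99 ± 0.21). Of 20 genes of manganese and iron handling, 8 rose and 1 fell (11 and 2 adjusted over the list alone, median 0.75), among them the manganese importer SLC39A14 (2.10 ± 0.22), the Golgi calcium and manganese pump ATP2C1 (2.10 ± 0.22) and the lysosomal ATPase ATP13A2 (2.09 ± 0.23). Camera with Benjamini-Hochberg adjustment gave adjusted p = 1.36e-28, 1.73e-29, 4.49e-29, 5.81e-21 and 0.000266 for these 5 lists in this order, and all 5 passed with an estimated correlation as well (adjusted p = 0.00204, 0.00204, 0.0271, 0.00204 and 0.0253).

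Mitochondrially encoded mRNAs were higher in the manganese input in 7 of 13 cases and lower in 0 (12 and 0 adjusted over the list alone, median 1.23), with MT-ND1 at 1.70 ± 0.28. The interferon response had 8 of 31 higher and 2 lower (8 and 2 adjusted over the list alone, median 0.44). KRAB zinc finger mRNAs had 10 of 141 lower and 0 higher (7 and 0 adjusted over the list alone, median -0.35), and ribosomal proteins 1 of 73 lower and 0 higher (0 and 0 adjusted over the list alone, median -0.16). Their camera tests gave Benjamini-Hochberg adjusted p = 4.83e-05, 0.0208, 1.21e-06 and 0.0131, and adjusted p = 0.387, 0.282, 0.112 and 0.74 with an estimated correlation. The interferon call was lost without control input 3 (0.079) or manganese input 1 (0.0574), and with total counts (0.163), where its median was -0.0021; without manganese input 2 its median was 0.28. The ribosomal call was lost without control input 3 (0.06), with fry (0.59) and on log2(TPM + 1) (0.065), and its median was -0.24 or -0.25 without manganese input 1 or 2. IFI6 (1.73 ± 0.29) rose and PARP9 (-1.10 ± 0.20) fell within the interferon list. NF-kB and inflammatory mediators had 6 of 26 higher and 0 lower (6 and 0 adjusted over the list alone, median 0.66), among them the cytokine LIF (2.13 ± 0.27) and CXCL8. Of 35 JNK pathway genes, 6 were higher and 0 lower (6 and 1 adjusted over the list alone, median 0.14). They included the MAP kinase phosphatase DUSP1 (3.12 ± 0.23), ATF3 (3.09 ± 0.33) and FOS (1.86 ± 0.26). Neither list passed (camera, Benjamini-Hochberg adjusted p = 0.0522 and 0.3).

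In total 2215 genes passed in the input, 1678 higher and 537 lower. The lower genes were 319, 286 or 287 without control input 1, 2 or 3, 1064 without control IP 3, 833 without manganese IP 3, 1144 with DESeq2 and 974 with the filter of 1 CPM. With total counts, where the median of all genes was -0.49 against -0.04, 1121 of 3742 genes were higher and 2621 lower. With only the 6 input libraries scaled and fitted, 2400 of 4266 were higher and 1866 lower (56.3% higher against 75.8%), and with the length correction 62.8% were higher. The secretory pathway list kept a median of at least 1.31 under each scaling. The 1545 enriched genes included 220 higher and 98 lower in the manganese input, with a median of -0.0097. The 1983 depleted genes included 249 higher and 31 lower, with a median of -0.019. Neither set passed camera of limma, and the depleted set's median and its test differed in sign.

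**Figure D3:**
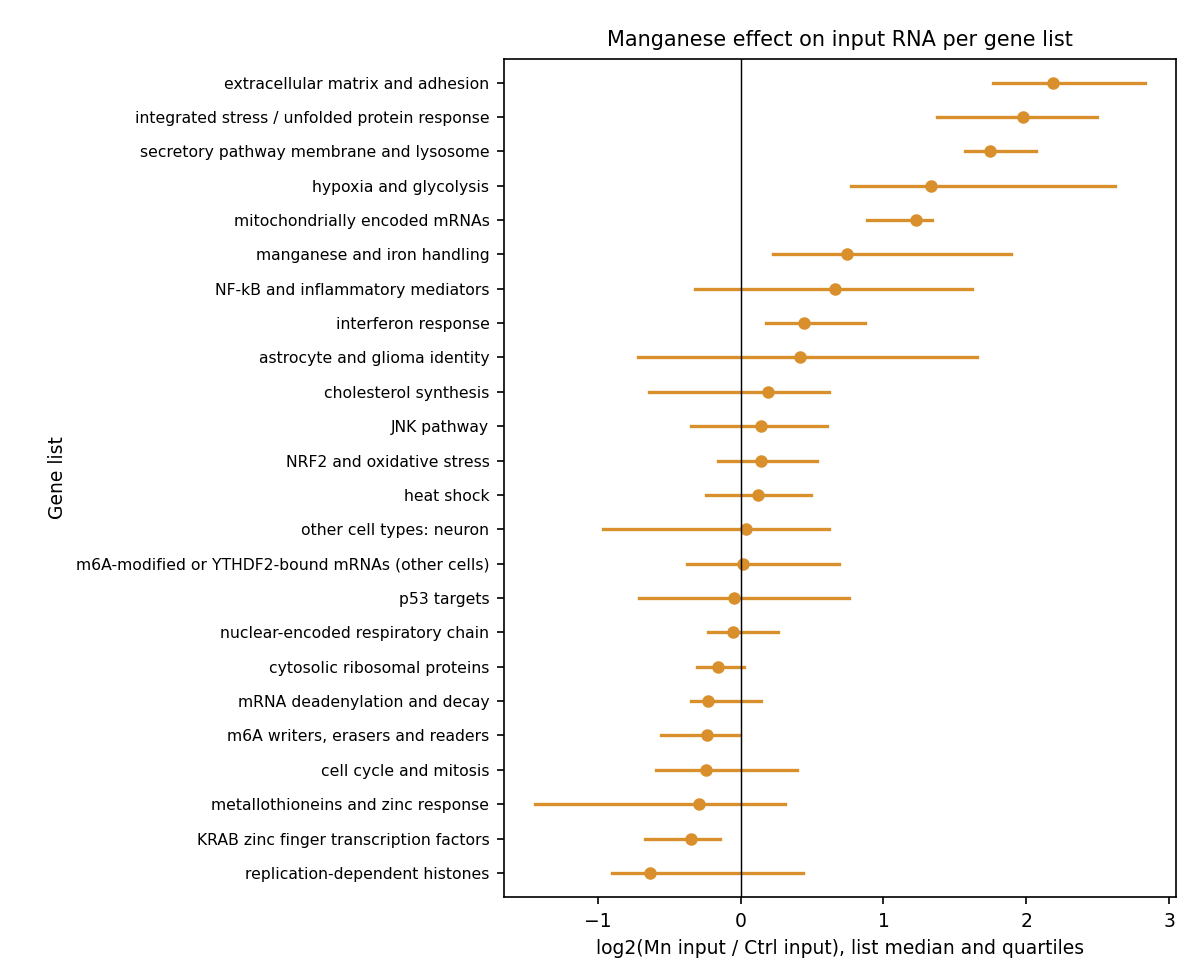
Median log2 change with manganese of the members of each gene list in the input, with lines from the lower to the upper quartile. Extracellular matrix genes lay at a median of 2.19 and KRAB zinc finger mRNAs at -0.35.

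The IP libraries of both treatments were also compared directly, which measures recovered RNA without regard to its level. SLC7A5 rose from 42.9 ± 2.34 to 833 ± 64.9 CPM, GPRC5A by 6.43 ± 0.29 and IL11 by 5.69 ± 0.30 on the log2 scale (n = 3). TPRG1 fell by 4.40 ± 0.32, the interferon-induced gene PARP9 by 2.70 ± 0.21 and MAP2K4 by 1.55 ± 0.18. YTHDF2 (-0.97 ± 0.16), MAPK9 (-0.95 ± 0.21) and MAPK8 (-0.90 ± 0.21) fell and JUN rose (0.53 ± 0.18). In edgeR with Benjamini-Hochberg adjustment, adjusted p was 1.22e-08 for SLC7A5, 1.91e-05 for MAP2K4, 0.000238 for YTHDF2, 0.00231 for MAPK9, 0.00309 for MAPK8 and 0.029 for JUN, the last of which was lost with total counts (0.15), with only the libraries compared (0.0626) and on log2(TPM + 1) with limma (0.0546), and was 0.33 without control IP 3. UPF1 and OGFOD1, at 0 counts in the manganese IP, were at least 309-fold and 289-fold lower than in the control IP, on the counts as assigned.

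KRAB zinc finger mRNAs were lower in the manganese IP in 104 of 141 cases and higher in 1 (106 and 1 adjusted over the list alone, median -1.50), among them ZNF184 (-2.44 ± 0.19) and ZNF436 (-2.37 ± 0.21). The integrated stress and unfolded protein response had 25 of 29 higher and 0 lower (25 and 0 adjusted over the list alone), with a median of 2.68, or 2.50 with genes of a group at 0 placed at their bound. Hypoxia and glycolysis had 23 of 34 higher and 3 lower (23 and 3 adjusted over the list alone, median 1.74), and extracellular matrix and adhesion 24 of 30 higher and 0 lower (24 and 0 adjusted over the list alone, median 2.28). These 4 lists passed camera with Benjamini-Hochberg adjustment (adjusted p = 3.13e-18, 5.85e-17, 4.03e-10 and 1.05e-13) and also with an estimated correlation (adjusted p = 0.018, 0.018, 0.018 and 0.0226). Ribosomal protein mRNAs were higher in 52 of 73 cases and lower in 2 (58 and 3 adjusted over the list alone, median 1.04), and the secretory pathway list in 34 of 39 and lower in 1 (35 and 1 adjusted over the list alone, median 1.97). The respiratory chain was higher in 26 of 53 and lower in 1 (26 and 1 adjusted over the list alone, median 0.86), and mitochondrially encoded mRNAs in 10 of 13 and lower in 0 (10 and 0 adjusted over the list alone, median 1.38). NRF2 and oxidative stress genes were higher in 14 of 26 cases and lower in 5 (14 and 5 adjusted over the list alone, median 0.90). Camera with Benjamini-Hochberg adjustment gave adjusted p = 5.11e-14, 1.07e-14, 9.95e-06, 0.000156 and 0.0106 for these 5 lists, and adjusted p = 0.404, 0.171, 0.447, 0.447 and 0.404 with an estimated correlation. The m6A writers, erasers and readers were lower in 11 of 22 cases and higher in 1 (11 and 1 adjusted over the list alone, median -0.76), with the reader YTHDC2 at -1.78 ± 0.17. Deadenylation and decay genes were lower in 12 of 26 cases and higher in 1 (12 and 1 adjusted over the list alone, median -0.97), with CNOT6, a deadenylase of the CCR4-NOT complex, at -1.28 ± 0.17. Camera gave Benjamini-Hochberg adjusted p = 0.0147 and 0.0328 for them, and adjusted p = 0.177 for both with an estimated correlation. Without control IP 3 the medians of the respiratory chain (0.52) and of NRF2 and oxidative stress (0.60) were lower. The decay call was lost with the filter of 1 CPM (0.0671) and with the length correction (0.0782).

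In total 6350 genes differed between the IP groups, 3020 higher and 3330 lower with manganese. With total counts these were 2428 and 4335 (35.9% higher against 47.6%), with a median of all genes of -0.37 against -0.09, and with only the libraries compared 2438 and 2229. Of the 1678 genes higher in the manganese input, 1171 were also higher in the manganese IP, against 342 for independent lists, and 51 were lower. Of the 537 lower genes, 436 were also lower in the IP, against 121, and 11 were higher. Over all genes r was 0.426 and rho 0.476, across genes, which are not independent replicates.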

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

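The tests of transcript length, scaling, single libraries, unselected RNA and the place of MAP2K4 among enriched mRNAs were chosen after the results were seen. So were the splits for the change of enrichment, while the other splits were chosen before. The test of membrane-protein mRNAs used a limit taken from the observed median of the secretory pathway list, so it was not fully fixed before.

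Enrichment of MAP2K4 fell by 1.48 on the log2 scale with manganese and that of YTHDF2 fell by 0.78, and both stood out because the difference between treatments itself passed the interaction test of edgeR. The same test over gene lists, with camera, singled out 5 lists by their median difference: 1.24 for cytosolic ribosomal proteins, 0.85 for the respiratory chain, 0.61 for NRF2 and oxidative stress, 0.56 for the integrated stress and unfolded protein response and -1.07 for KRAB zinc finger mRNAs. The calls of all 5 lists were lost with an estimated correlation. Another result stood out as a signal in the transcript table, which no comparison used. PCGF6 held a median of 36.3% of the gene counts over the 12 libraries, and the most abundant transcript held at least 99.99% of that count in each library, by which alone it was matched to PCGF6, since no table pairs them. It had a median of 0.137 of the counts per TPM of the median transcript, a ratio that follows length. A median of 3.19% of the transcripts compared were as short.

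With manganese, ribosomal protein mRNAs became less depleted and KRAB zinc finger mRNAs less enriched in the IP. After the correction for transcript length the KRAB median was -0.82 and the ribosomal median 1.08, and without control IP 3 they were -0.96 and 0.91, which argues against a length trend or that library as the whole cause. The KRAB list passed under each alternative run except camera with an estimated correlation (Benjamini-Hochberg adjusted p = 0.133). A larger share of unselected RNA in the manganese IP would, by itself, narrow the spread of enrichment. The ratio of its noise-corrected SDs, manganese over control, was 1.03 (95% bootstrap interval 0.995 to 1.07, 3549 genes). Other differences between the IPs can widen that spread, so the ratio does not decide and this explanation stays open. The ribosomal (-2.10 in control, -0.80 in manganese) and KRAB medians (1.01 and 0.06) both moved towards the input. An action of manganese on the association of these mRNAs with YTHDF2 may account for the pattern and stays open, as does any difference between the IPs that follows the treatment, since no IP with a control antibody was analysed.

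MAP2K4 lost enrichment with manganese while its level in the input had a log2 change of -0.06 ± 0.18. Over the scalings tried the smallest loss was -1.31, and without control IP 3 the change was -1.52, which argues against the scaling or that library as the cause; over 24 alternatives the change lay between -1.58 and -1.12 (edgeR, limma or DESeq2, Benjamini-Hochberg adjusted p from 8.51e-07 to 0.0119). The 1545 mRNAs enriched on average showed no general loss of that size, with a median change of -0.13 (quartiles -0.66 and 0.45). Choosing by the average favours mRNAs that kept enrichment, so this does not decide for mRNAs enriched in control. Among 1678 genes enriched in control, 397 lost and 9 gained enrichment, and the median went from 1.45 to 0.96. These were chosen on libraries that enter the change as well, which inflates losses. Even so their median stayed at 0.96, which argues against a loss of that size in most of them. An ordinary place among the changes of the 1545 mRNAs stays open, since MAP2K4 stood at percentile 5.24 of that set, whose 5th percentile was -1.52. It stood at 1973 of all 14804 genes counted from the largest loss. A specific release of MAP2K4 mRNA from YTHDF2 with manganese may be among the explanations and was not tested.

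In the manganese input, mRNAs of the secretory pathway, lysosome and extracellular matrix rose. The smallest median of the secretory pathway list over the scalings was 1.31, and without control input 1 it was 1.88, which argues against these as the cause. Better recovery of membrane-bound mRNAs from the manganese lysates would raise membrane-protein mRNAs in general. The 386 genes named TMEM or SLC, without the mitochondrial SLC25 family, had a median of 0.80 (bootstrap interval 0.68 to 0.98). That interval spans the limit of 0.87, which was taken from the observed median of the secretory pathway list. Of the TMEM and SLC genes 128 were higher and 4 lower (33.2% higher, against 10.8% of 14418 other genes). A difference in recovery from the cleared lysate and a regulation of these genes by manganese may both contribute. They cannot be told apart, since the input of a cleared lysate reflects level and recovery together. No outcome against that limit could have separated them.

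Counts of genes that passed were compared with other splits of the same libraries. For enrichment averaged over both treatments, 1 of 80 splits drawn, the real one, gave as many genes (6237, highest other 2629). A share of 1 in 80 is the smallest that these splits can give, so a chance arrangement was unlikely but not excluded. For the change of enrichment, with inputs and IPs split independently, 6 of 80 splits drawn, the real one included, gave as many genes (2531, highest other 6209). The 5 others point to a structure of the samples, since each set the 3 control IPs whole against the 3 manganese IPs, so that the difference between the IPs of the treatments enters their counts. Splits that mixed the IP groups gave 0 genes. The share of 6 in 80 is thus no measure of chance for this comparison, and a chance arrangement is not excluded. For the other 4 comparisons 10 splits exist, of which 1, the real one, gave as many, and these are too few for a share under 0.05. The real and the highest other counts were 4639 and 0 for enrichment in control, 4795 and 0 in manganese, 2215 and 1 between inputs, and 6350 and 1 between IPs.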

How the results depend on the processing

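Limma on log2(TPM + 1), scaling without PCGF6 and ENSG00000226958, the length correction and leaving out control input 1 and control IP 3 together were chosen after the data were seen. Of 692 gene results, 554 held their direction and side of the threshold under each alternative run, and 138 did not under at least 1. Of 48 list calls, 9 held throughout, 39 were lost with an estimated correlation and 0 reversed. Gene calls were lost 66 times on log2(TPM + 1), 43 times with the length correction, 30 times with total counts, 21 with limma voom, 18 without the low-count filter, 10 with only the libraries compared, 8 without both control libraries, 6 with scaling without PCGF6, 5 with the filter of 1 CPM, 3 with DESeq2, 3 with RLE factors and 1 with TMM without the 100 most abundant genes. Leaving out 1 library at a time ended gene calls 295 times in all. Gene counts summed from transcripts and tests of single transcripts were not run, and DESeq2 has no form of the set tests. Except where stated, the cause was not tested.

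With total counts, MAPK9 in control enrichment was -0.28, YTHDF2 in manganese enrichment -0.016, JUN in the input -0.038, and 3742 genes passed in the input. With only the libraries compared, MAPK9 in control enrichment was -0.11 and 4266 genes passed in the input. On log2(TPM + 1), MAPK9 in control enrichment was -0.16, and in average enrichment MAP3K13 was -0.34 (0.86 in edgeR), MDM2 -0.57 (0.81) and GLUL -0.043 (0.90). Without control input 1 and control IP 3 together, MAPK9 in control enrichment was -0.17, JUN in the change of enrichment -0.079, and 3998 genes changed enrichment. With the length correction, ZMAT3 in control enrichment was -0.21 (0.56 without it) and MAPK9 in average enrichment 0.11 (-0.38).

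The sets of enriched and depleted genes gave no stable direction. The direction of the test on the enriched genes in the input turned with fry (median -0.0097), on log2(TPM + 1) and without both libraries (median 0 in either) and for a set threshold of 2 (0.10). For the depleted genes there it turned at that threshold (-0.049), and fry passed upward although the median was -0.019. In the change of enrichment the test on the enriched genes turned with RLE factors (-0.062), total counts (0.056), no filter (-0.12), a set threshold of 2 (-0.016), log2(TPM + 1) (-0.019), scaling without PCGF6 (-0.024) and the length correction (0.095), and it passed as a loss without both libraries (-0.31). That on the depleted genes turned with fry (-0.34), a set threshold of 2 (-0.79), log2(TPM + 1) (-0.23) and the length correction (-0.59), with which it passed as a loss.

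Leaving out each library in turn gave -0.13 to 0.14 for MAPK9 in control enrichment and -0.081 to 0.30 for JUN in the change of enrichment. The set medians ran from -0.13 to 0.019 (enriched, input), -0.29 to 0.038 (enriched, change) and -0.59 to 0.048 (depleted, change). Counts ran from 1455 to 3765 for the change of enrichment, 3504 to 5821 for control, 3638 to 5964 for manganese, 5452 to 7355 for the average, 1500 to 3213 for the input and 5576 to 6605 for the IP, each highest without control IP 3.

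With the replicate number as a block, 4334, 4475, 5925, 1670, 5351 and 2157 genes passed for enrichment in control, in manganese and on average, manganese in the input and in the IP, and the change of enrichment, and 22 of the gene calls and 2 of the list calls were not made. The genes included MAPK9 in average enrichment (edgeR, adjusted p = 0.0979) and JUN between the IPs (0.0663). The lists were cholesterol synthesis in control (camera, adjusted p = 0.0916) and in manganese enrichment (0.0679). Deviations from group means of libraries sharing a number correlated by -0.460 to 0.0865 between inputs, -0.255 to 0.0312 between IPs, 0.0372 to 0.236 between control input and IP and -0.0166 to 0.0764 between manganese input and IP. With 3 libraries per group, these correlations do not decide whether libraries of the same number share a lysate. In simulated counts with few changed genes, 23% of changes of 2 and 3% of changes of 1 on the log2 scale were called for the change of enrichment, and what was missed in the real data was not measured.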

Other observations

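The gene lists were fixed before the data were examined, and the mitochondrial shares, the values of ENSG00000226958 and the comparison with the authors' table were chosen after the data were seen. In the manganese input, genes of astrocyte and glioma identity moved apart. Of 24 measured, 8 were higher, 4 lower and 12 did not pass (8 and 6 adjusted over the list alone, median 0.41), with GFAP at -3.02 ± 0.20 and NES, SERPINA3, a protease inhibitor of reactive astrocytes (2.02 ± 0.21), and CLU, clusterin (1.73 ± 0.19), higher. Of 26 genes of NRF2 and oxidative stress, 5 were higher and 2 lower (5 and 2 adjusted over the list alone, median 0.14), with HMOX1, heme oxygenase, at 2.17 ± 0.17 and SLC7A11, the cystine transporter, at 1.41 ± 0.20. Of 7 metallothionein and zinc response genes, 0 were higher and 2 lower (1 and 2 adjusted over the list alone, median -0.29), the lower ones being MT1E (-2.23 ± 0.28) and MT1F (-2.25 ± 0.41). Among 36 genes of cell cycle and mitosis, 3 were higher and 6 lower (3 and 7 adjusted over the list alone, median -0.24), with the replication factor CDC6 (1.38 ± 0.17) and the ribonucleotide reductase subunit RRM2 (1.24 ± 0.19) higher, and the mitotic genes CCNB1 (-1.10 ± 0.21) and AURKA (-0.88 ± 0.17) lower. Of 17 p53 targets, 1 was higher and 4 lower (2 and 4 adjusted over the list alone, median -0.05), with the death receptor TNFRSF10B at 1.87 ± 0.18 and ZMAT3 (-1.02 ± 0.15) and TP53INP1 (-1.05 ± 0.18) lower. None of these 5 lists passed camera in the input (Benjamini-Hochberg adjusted p = 0.323, 0.305, 0.0942, 0.165 and 0.564).

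Heat shock genes in the manganese input were higher in 3 of 18 cases and lower in 1 (4 and 1 adjusted over the list alone, median 0.12), the lower one being the chaperone HSPH1 (-0.95 ± 0.17). Cholesterol synthesis genes were higher in 3 of 22 and lower in 1 (3 and 2 adjusted over the list alone, median 0.19), with the sterol isomerase EBP at 1.79 ± 0.26. Of 10 replication-dependent histones 0 were higher and 0 lower (0 and 0 adjusted over the list alone), with a median of -0.64. Camera gave Benjamini-Hochberg adjusted p = 0.831, 0.745 and 0.147 for these 3 lists. Of 7 neuron markers 0 were higher and 1 lower (0 and 1 adjusted over the list alone, median 0.04; camera, Benjamini-Hochberg adjusted p = 0.783, with the test pointing down), the lower one being MAP2 (-1.01 ± 0.24). Lists with fewer than 5 measured members were not tested as lists: of 3 microglia and macrophage markers 1 was higher, CD68 of lysosomes (2.78 ± 0.27), with a median of 0.86, of 4 epithelial markers 0 passed (median 0.51), and of 3 non-polyadenylated and nuclear RNAs 0 passed (median -0.16).

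Enrichment of single genes on other lists changed with manganese. Of 7 metallothionein and zinc response genes, 5 gained and 1 lost enrichment (5 and 1 adjusted over the list alone, median 2.17), among them MT2A (2.15 ± 0.44), and the zinc exporter SLC30A1 lost it (-1.73 ± 0.37). Between the IP groups the median log2 change of these 7 genes was -0.06. Of 24 astrocyte and glioma genes, 6 gained and 0 lost (6 and 0 adjusted over the list alone, median 0.23), among them TIMP1, an inhibitor of matrix proteases (2.36 ± 0.35), GFAP (1.61 ± 0.26, with a lower level in the manganese input) and CLU (1.61 ± 0.27). Neither list passed camera (Benjamini-Hochberg adjusted p = 0.0602 and 0.0599). COL6A2, a collagen of the extracellular matrix, gained 2.92 ± 0.47, and the heat shock gene HSPA4L lost enrichment (-1.71 ± 0.26).

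Mitochondrially encoded mRNAs made up 2.28% to 2.96% of the gene counts in the control input and 3.72% to 4.36% in the manganese input. ENSG00000226958 held 3.58% of the counts in control IP 3 and at most 0.211% in the other libraries. In the authors' deposited table, the mean log2 ratios of IP to input were 0.649 in control and -0.0690 in manganese for YTHDF2, 1.11 and 1.32 for JUN, -0.543 and -1.34 for MAPK9, and 0.199 and 0.0549 for MAPK8. Of 17607 genes with a p-value there, 3186 had an unadjusted p under 0.05. Of 108 genes named by size of change or in any case, 12 had a group with 3 libraries at 0. Of 162 pairs of list and comparison, 28 held members with such a group, and placing them at their bound moved a list's median by at most 0.18.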
